A study of Gallus gallus with 16 samples.

How the data were processed

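RNA of chicken embryonic pituitary glands was profiled on two-colour cDNA microarrays at embryonic days 10, 12, 14 and 17 (E10, E12, E14 and E17), with 4 biological replicates per age and 16 arrays. Per the labels, each replicate was a pool of glands from 16 embryos at E10, 8 at E12, 4 at E14 and 2 at E17, and 500 ng of RNA was amplified. The amplified sample carried Cy3 and was hybridised with a Cy5-labelled reference pool to which each of the 16 samples gave 2 µg. All 16 samples had an age in the labels and entered every comparison unless a left-out array is named.

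The values used are the authors' deposited log ratios, 1 per spot and array, read as log2 of sample over reference pool. Image analysis, background correction, normalization and spot filters are not given in the sources used here. The deposited columns themselves were centred and scaled: array means lay between -0.0065 and 0.0025, medians between -0.023 and 0.036, and the SD of every array between 0.2612 and 0.2614. A difference is therefore a difference in scaled log ratios, and no fold changes are given. The scanner intensities were not analysed here.

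Direction and log base are not stated with the values and were checked from the design. The pool held equal amounts of all 16 samples, so the mean over ages of the linear sample-to-pool ratio should vary little from probe to probe. Among 51 probes whose means varied most between ages (variance above 0.5), the mean of 2 raised to the value had a median of 0.915 and an SD of 0.1 on the log2 scale, against 1.51 and 0.33 with the sign turned. The regression slope of the mean value on the between-age variance was -0.32. The ratios were taken as sample over pool, which is also the order in which the sample titles name them. The labels give the dye of each but do not say which dye was divided by which. The base with the least spread was 2.19 (bootstrap interval 1.96 to 2.66, 1000 draws). Base 10 gave a wider spread, 0.201, while natural logarithms, at 0.108, were close to base 2. Their median of the mean ratio, 1.006, was nearer than that of base 2 to the 1 of an equal pool, a level that centring and scaling can shift. Base 2 is therefore an assumption, and every log2 value given is a deposited value read on that scale. Some arrays of different ages correlated below 0, down to r = -0.369 between an E10 and an E17 array across probes. The ages can oppose each other around a pool of all ages, so the direction was kept.

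The table has 7200 rows, and 7023 to 7194 of them held a value on each array. On 4 arrays, E12 replicates 3 and 4 and E14 replicates 3 and 4, 39 to 45 of the first 45 spots were blank, against 0 or 1 on the other 12. These arrays were treated as a possible batch, since both ages are present on either side. Probes with at least 3 values in every age were tested, 7103 in all, and 97 rows were left out, among them 6 with no value on any array. The arrays' number, 4 per age, limits the precision: the median standard error of a difference between 2 ages was 0.12.

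The platform annotation given here names 54 of the 7200 rows, all of them STUB1, and leaves 7146 unnamed here; no row has several genes. The 27 gene lists fixed beforehand, which covered pituitary hormones, transcription factors, receptors, secretion, the cell cycle and other tissues, could not be tested for that reason. The rule for named genes also could not be applied, and its place was taken by at most 2 probes that rose most and 2 that fell most among those past the threshold in each comparison, given by row number.

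Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a mean per age and 1 residual variance per probe over all 16 arrays. A moderated F test covered any difference among the 4 ages, and contrasts covered each consecutive pair of ages and E17 against E10. P values were adjusted by the Benjamini-Hochberg method over the 7103 probes, at a threshold of 0.05. Probes past the F test were grouped by k-means on their standardised age means (6 groups). To place each array between the youngest and oldest glands, its values were projected on the difference between E17 and E10 over the probes past that contrast in a fit of those 2 ages, leaving the array itself out where it belonged to either age. Positions were compared by two-sided exact permutation tests, for which 0.0286 is the smallest p with 4 arrays against 4. The scale was not rebuilt in the permutations.

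The fitting was tested on simulated data with 100 probes changed by 0.5 and 100 by 1. Noise was normal and independent between probes and arrays, the changes were in 1 age, and each setting was run once. The real arrays had deviations shared between arrays, so the rates need not carry over to them. With the spread set as measured in each age, 57 to 68% of the smaller and 95 to 99% of the larger changes were recovered over the 4 contrasts. False calls were 3% of the calls for E12 against E10, 1.9% for E17 against E10, 11.2% for E14 against E12 and 11.9% for E17 against E14, against 5.7% and 5.2% for the latter pair when the simulated spread was equal in all ages. For the F test they were 6.5 to 9.1% of the calls with the spread as measured, and 3.7 to 7.3% with equal spread.

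Replicate numbers were shared by the ages in the labels. For E14 against E12, deviations from the age means correlated above 0.1 in 4 of 4 same-number pairs of arrays (0.148 to 0.437 across probes). The numbers were therefore taken as pairs for that comparison alone, a decision made after its counts were known. No other comparison met this for all of its pairs. Among E12 and E14 pairs of unlike number, E12 replicate 4 with E14 replicate 2 (0.207) and E12 replicate 1 with E14 replicate 3 (0.178) also passed 0.1. The first of these was above the same-number pair of E12 replicate 4 (0.148). The other unlike pairs lay between -0.351 and 0.088. The shared deviations therefore did not follow the replicate number alone. The SEs and p values given for E14 against E12 still come from the fit without pairs. The fit with the replicate number as a block is given as an alternative.

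Designs, alternatives and sample groups were fixed before the data were examined. The alternatives were median centring, quantile normalization, stricter and looser filters on blank spots, the replicate number as a block, array weights, robust moderation, a fit without moderation, fits of only the ages compared and leaving out each array in turn. Alternatives chosen after seeing the data were the blank-block batch as a term, leaving out its 4 arrays, and odd or even replicate number as a term.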

Results

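Gene expression was compared in pituitary glands of chicken embryos at E10, E12, E14 and E17, a period that the study's title links to the differentiation of thyrotrophs, somatotrophs and lactotrophs, the cells that make thyrotropin, growth hormone and prolactin. Each age had 4 replicate pools, of 16 embryos at E10, 8 at E12, 4 at E14 and 2 at E17, and every array measured 1 sample against the same reference. Between 7023 and 7194 spots per array held a value. Values are scaled log2 ratios of sample over reference, and probes are given by row number because the annotation used here names no gene for them.

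Of 7103 probes tested, 901 (12.68%) differed among the 4 ages by limma's moderated F test. Probes that were highest in the youngest or the oldest glands made up most of these: 402 had their highest mean at E10 and 354 at E17, against 47 at E12 and 98 at E14. The means of 329 probes were lower at each age than at the one before, and those of 253 were higher, which together is 64.6% of the 901. The step with the largest change was E10 to E12 for 287 probes, E12 to E14 for 304 and E14 to E17 for 310. Per day, it was the longer last interval for only 200, against 337 and 364.

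The 901 probes fell into 6 groups by the shape of their time course. The largest, 284 probes, fell from 0.24 ± 0.03 at E10 to -0.31 ± 0.03 at E17 (mean over probes ± SD over arrays, n = 4), passing 0.01 ± 0.07 at E12 and -0.19 ± 0.07 at E14. A second group of 210 probes went the opposite way, from -0.58 ± 0.05 at E10 through -0.18 ± 0.10 and 0.15 ± 0.16 to 0.26 ± 0.06 at E17. In 166 probes the decrease came late, with 0.19 ± 0.03 at E10, 0.12 ± 0.09 at E12, 0.00 ± 0.08 at E14 and -0.36 ± 0.03 at E17. In 158 probes the increase began after E12, with means of -0.55 ± 0.05, -0.48 ± 0.05, 0.05 ± 0.17 and 0.45 ± 0.04. A smaller group of 50 probes stayed low through E14, at -0.47 ± 0.06, and stood at 0.53 ± 0.08 at E17. The last 33 probes were highest at E14, at 0.34 ± 0.08, and returned to -0.08 ± 0.07 at E17. The groups were formed from the same values that their means describe.

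**Figure D1:**
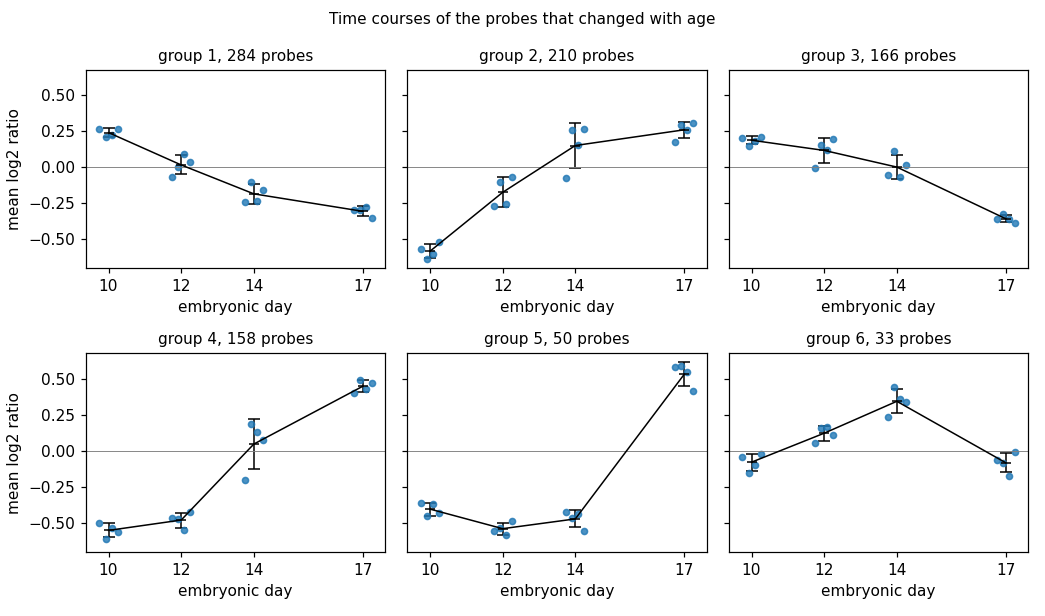
Mean log2 ratio (sample over reference) of the probes in each of the 6 time-course groups, plotted against embryonic day. Points are the 4 arrays of an age, lines join the age means and bars are the SD over arrays; the 50 probes of group 5 stay below 0 through E14 and reach 0.53 at E17.

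The oldest glands were compared with the youngest to give the full extent of the change. Probes lower at E17 outnumbered those that were higher, 722 against 472 of 1194 past the threshold, but the increases were larger. Among them, 138 increases and 11 decreases were of at least 1 on the log2 scale, and the median size was 0.70 for increases and 0.46 for decreases. Probe 1621 rose by 3.33 (SE 0.20, limma adjusted p = 8.4e-09), from -1.72 ± 0.08 at E10 to 1.61 ± 0.31 at E17 (SD, n = 4). Probe 4935 rose by 3.22 (SE 0.24, limma adjusted p = 8.93e-08), and stood at 0.09 ± 0.58 at E14, where replicate 1 lay apart at -0.766. Probe 4970 fell by 1.83 (SE 0.15, limma adjusted p = 3.13e-07) and probe 171 fell by 1.63 (SE 0.10, limma adjusted p = 1.24e-08). With each array's median subtracted the split was 505 higher and 611 lower. The deposited arrays were centred on their means, so large increases are offset by decreases in other probes. The split therefore depends in part on the centring. Array weights raised the count of changed probes to 1887, and a fit of these ages alone raised it to 1617.

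**Figure D2:**
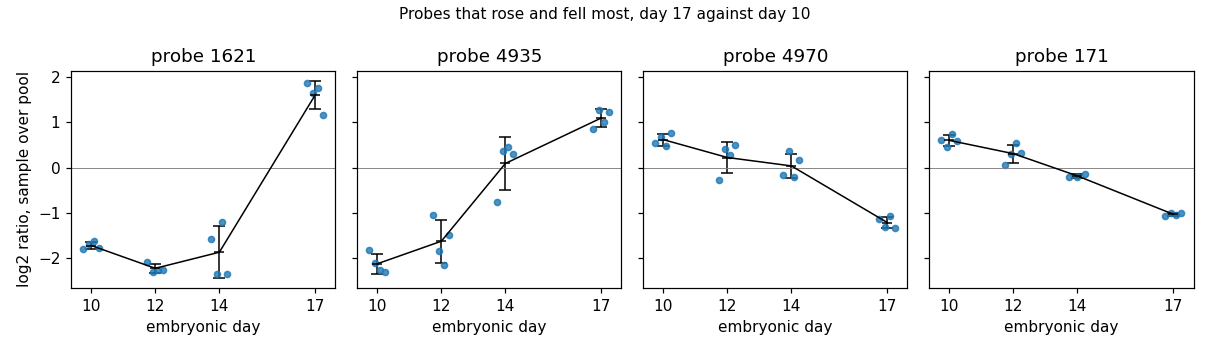
Log2 ratio (sample over reference) of the 2 probes that rose most and the 2 that fell most from E10 to E17, plotted against embryonic day. Points are single arrays, lines join the age means and bars are the SD over arrays; probe 1621 lies below -1 on all arrays up to E14 and between 1.167 and 1.871 at E17, and probe 171 has 3 values at E14.

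Between E10 and E12, the first interval, 28 probes changed, of which 21 rose and 7 fell. Probe 5598 rose by 1.21 (SE 0.20, limma adjusted p = 0.00913), from -1.47 ± 0.14 to -0.26 ± 0.25 (SD, n = 4), and probe 5011 rose by 1.05 (SE 0.20, limma adjusted p = 0.0422). Probe 693 fell by 0.69 (SE 0.11, limma adjusted p = 0.00913) and probe 6600 fell by 0.50 (SE 0.10, limma adjusted p = 0.0422). At an unadjusted p under 0.05 there were 678 probes. The count depended on single arrays and settings: leaving out 1 array gave 2 to 48 probes (0 to 11 of them lower), array weights gave 64, odd or even number as a term 55, the fit without moderation 7, the blank-block batch as a term 5 and quantile normalization 4, and limma called 0 without the 4 arrays of that batch (827 at an unadjusted p under 0.05). Each of the 4 named probes lost the threshold without the batch's arrays, with 2 arrays left at E12, while their differences were 1.18 (probe 5598), 1.02 (probe 5011), -0.76 (probe 693) and -0.45 (probe 6600); probe 693 had 1 array apart from the others at E10 and at E12.

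Between E12 and E14, 49 probes rose and 7 fell in the fit without pairs (60 and 10 with the replicate number as a block). All 49 were also higher at E17 than at E10, and 13 of them rose again between E14 and E17. Independent lists would share 0.421 probes, a figure that leaves out the E14 arrays common to both steps. Probe 5037 rose by 2.21 (SE 0.27, limma adjusted p = 0.000804), from -2.02 ± 0.27 to 0.19 ± 0.83 (SD, n = 4). Probe 5909 rose by 1.98 (SE 0.21, limma adjusted p = 0.000187), from -1.80 ± 0.36 to 0.18 ± 0.47. Probe 585 fell by 0.57 (SE 0.13, limma adjusted p = 0.0463) and probe 5991 fell by 0.55 (SE 0.12, limma adjusted p = 0.0273). Within the blank-block batch 34 probes passed and within the other arrays of both ages 1, and the differences of the batches correlated at r = 0.318 across probes; with the batch as a term 58 passed, 54 of them among the 56. Without E14 replicate 1 the count was 138, and in a fit of these ages alone it was 17 (17 higher and 0 lower). Dividing the same 8 arrays into odd and even replicate numbers called 423 probes in the fit of all 16 arrays, more than the ages did. In a fit of these 8 arrays alone, a term for odd or even number beside age called 0. Of the 4 named probes, probe 5909 alone stayed past the threshold in every fit tried. Over 12 alternatives, probe 5037 kept it in 11 (difference 1.861 to 2.364), probe 5991 in 8 (-0.572 to -0.526) and probe 585 in 6 (-0.594 to -0.514). With each of the 16 arrays left out, they kept it in 16, 12 and 2 runs.

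Between E14 and E17, 61 probes rose and 51 fell. Probe 1621 rose by 3.48 (SE 0.20, limma adjusted p = 4.11e-09), having stood at -2.22 ± 0.10 at E12 and -1.87 ± 0.57 at E14 (SD, n = 4). Probe 539 rose by 3.11 (SE 0.17, limma adjusted p = 1.97e-09), from -1.74 ± 0.40 to 1.37 ± 0.22. Probe 4970 fell by 1.25 (SE 0.15, limma adjusted p = 8.45e-05) and probe 3725 fell by 1.01 (SE 0.13, limma adjusted p = 0.000189), the latter from its highest mean, 0.33 ± 0.33 at E14, where replicate 1 lay apart at -0.166. The change over this interval differed from that between E10 and E12 for 40 probes, of which 30 had the higher value in the last interval (limma, adjusted over all probes). The count was 69, 72 and 57 without E17 replicates 2, 3 and 4, and 42 in a fit of these ages alone. In some fits the decreases shrank more than the increases, to 18 against 39 without E17 replicate 4 and to 11 against 31 in the fit of these ages alone. Without E14 replicate 2 there were 28 decreases and 65 increases. Not every fit went this way: there were 71 decreases and 65 increases without E14 replicate 1, and 56 and 48 in the fit without moderation.

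The arrays of the middle ages lay between those of the youngest and oldest. On a scale from 0 at the E10 mean to 1 at the E17 mean, E12 arrays stood at 0.243 ± 0.069 and E14 arrays at 0.598 ± 0.068 (SD, n = 4), against 0.034 ± 0.014 at E10 and 0.956 ± 0.031 at E17. Each age lay above the one before without overlap (two-sided exact permutation p = 0.0286 for each step, the smallest that 4 against 4 allow). Only for E14 against E12 was the scale built from neither age compared. In the first and last steps 1 of the ages also set an end of the scale, so their separation is partly built in. At E12 the arrays with the blank block stood at 0.141 and 0.278 and the others at 0.29 and 0.262; at E14 they stood at 0.668 and 0.61 and the others at 0.506 and 0.606.

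**Figure D3:**
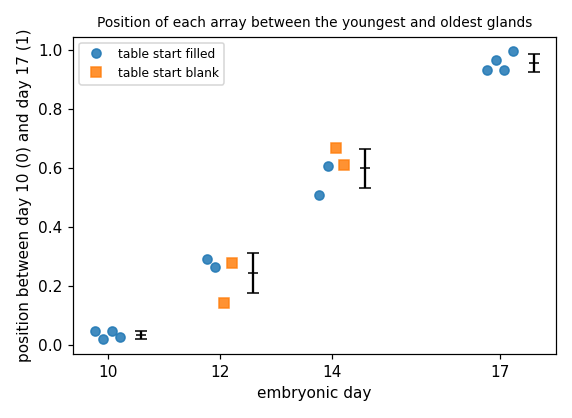
Position of each of the 16 arrays between the E10 mean (0) and the E17 mean (1), without unit, plotted against embryonic day. Circles are arrays with a filled start of the table, squares the 4 arrays with a blank start, and bars the mean and SD of each age; the ages do not overlap.

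In the scaled values, replicates were less alike at the middle ages. The median SD over probes was 0.113 at E10, 0.165 at E12, 0.186 at E14 and 0.136 at E17, and the median correlation between arrays of 1 age, across probes, was 0.596, 0.314, 0.174 and 0.494. The spread at E14 was 1.64 times that at E10. Probes are not independent replicates, and pool size differed with age, so the spread was not tested. Arrays that resemble the reference pool of all ages hold less signal. Their correlations can then be lower, and scaling to a common SD can enlarge their spread. The deposited values cannot separate this from a real difference between replicates.

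The 54 spots annotated as STUB1, a ubiquitin ligase that works with heat shock proteins, did not differ from randomly drawn spots in 2 measures. The median correlation between pairs of them was -0.006, inside the range of -0.024 to 0.029 for 1000 random sets of spots, and their SD within an array, 0.237, was inside the random range of 0.212 to 0.334. No level or change is therefore given for the gene.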

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

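The tests on odd and even replicate numbers, on scaling and on E14 replicate 1 were chosen after the results were seen. For array batches and uneven progress, the tests over all pairs and all probes and the test on pool size were set beforehand, and those on odd with even pairs and on probes far from the threshold were not. Also set beforehand were the counts over other splits of the arrays.

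In 75 groups of 4 arrays, 8 had a value far from the other 3, where chance gives about 3.8 (1 in 20). At E14, 3 of them were replicate 1: probe 585 at -0.857 (others -0.32 to -0.214), probe 3725 at -0.166 (others 0.469 to 0.505) and probe 4935 at -0.766 (others 0.3 to 0.465). Probe 693 stood apart at E10 (0.254 on replicate 3), at E12 (-0.429 on replicate 1) and at E17 (-0.682 on replicate 2). Probe 539 was at 1.04 on E17 replicate 4 against 1.44 to 1.51 on the other arrays. The 11 of the 30 probes that rose most whose largest step was E14 to E17 averaged -1.24 on E14 replicate 4, against -0.877 to -0.807 on the others.

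E14 replicate 1 was low in 17 probes that rose from E12 to E14: its mean was -0.843, against 0.227 to 0.514 on the other E14 arrays, and it was the lowest E14 array for 17 of 17. A mislabelled E12 sample is argued against by its position on the scale from E10 to E17 built without the 30 probes that rose most, which include these 17. The position was 0.584, which is 0.218 above the highest E12 array (SD of E12 positions 0.075) and near the lowest other E14 array at 0.608. Handling shared with E12 replicate 1 stays open: that array lay 0.243 above the lowest other E12 array in the 17 probes, but they had hardly risen by E12, so a lowered signal would not show there. The 2 arrays correlated at 0.597 over all probes (0.437 in deviations from the age means), and E14 replicate 1 at no more than 0.266 with its own age. Pairs of E14 arrays correlated at -0.006 to 0.339, with a median of 0.174, so the value of 0.266 does not set replicate 1 apart within its age. The value of 0.597 with E12 replicate 1 does stand out. It was above the highest pair within E12 (0.427), E14 (0.339) and E17 (0.576), though not within E10 (0.652). A less advanced pool of embryos, or another fault of this array, was not tested.

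Spread between replicates was highest at E14. Uneven progress along the age scale is argued against as the whole cause: among 1803 probes with an unadjusted limma p over 0.5 for E17 against E10, E14 was still at 1.432 times E10 (1.397 to 1.595 with arrays left out), while removing the scale's component moved the spread over all probes too little to be a test (E14 at 1.637 times E10). Array batches stay open: arrays of different batches differed 0.932 and 0.923 times as much as arrays of one batch at E12 and E14, but pairs of one batch always join an odd and an even number, and among such pairs alone the ratios were 1.007 and 1.058. Fewer embryos per pool predicted a rise through E17; E17 pools, the smallest, were 1.197 times E10 but 0.731 times E14, so pool size is not excluded, though alone it would not give an order that peaks at E14. Scaling every array to a common SD could have enlarged E14 arrays. If the error was equal before scaling, the factor would have to be 1.433. That figure is the observed E14 to E10 ratio itself, taken from mean variances, and so is no estimate of what scaling did. The deposited values cannot separate scaling from a real difference. Taking out the odd and even means left E14 at 1.285 times E10, between the bounds set for and against it, and biological variation at E14 was not tested.

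In the fit of all 16 arrays, the split of the E12 and E14 arrays into odd and even replicate numbers called 423 probes. Of them, 252 were higher on odd and 171 on even numbers, which points to a structure of these arrays. In a fit of the E12 and E14 arrays alone, a term for odd or even number beside age called 0, so the count depended on the fit. The odd minus even difference had the same sign in the pooled E10 and E17 arrays for 77.8% of the 423 probes (r = 0.587 across probes). This met the bounds first set for handling shared by number. A second test, added once that value was known, showed that 9 of 36 ways of halving the E10 and E17 arrays correlated as highly. Shared handling is therefore possible but not separated from the arrays' other differences. Array scores for this difference did not part odd from even numbers at E10 (odd -0.136 and 0.117, even 0.025 and -0.006). They did at E17 (odd 0.129 and 0.123, even -0.303 and 0.051), where replicate 2 lay furthest from the others. By these scores the agreement lay at E17 and not at E10. Over all 16 arrays, limma, the tool used, called 0 probes for odd against even (1335 at an unadjusted p under 0.05). The called probes had 38 neighbouring pairs in the table, between the median of 25 and the highest of 42 in 1000 random sets, so a place effect on the slide stays open, and no biological explanation was tested.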

How the results depend on the processing

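Terms for the blank-block batch and for odd or even numbers, and the fit without the 4 blank-block arrays, were chosen after seeing the data; the others were planned. The count for any age stayed between 838 and 1277 and the other counts stayed within 1.5 times their values, except as follows and with the replicate block. For E12 against E10 (28), quantile normalization gave 4, array weights 64, the fit without moderation 7, the batch term 5, the odd or even term 55, and leaving out the batch's arrays 0. For E14 against E12 (56), a fit of these ages alone gave 17 and leaving out the batch's arrays 1. For E17 against E14 (112), a fit of these ages alone gave 42, and for E17 against E10 (1194) array weights gave 1887. Fewer arrays entered the fits of 2 ages and those without the batch. That alone does not always lower a count, since the fit of E10 and E17 alone raised it from 1194 to 1617. Fits of 2 ages also take their residual variance from those ages alone. The median SD was 0.113 at E10, 0.165 at E12, 0.186 at E14 and 0.136 at E17. The cause of the changes was not tested. Robust moderation changed no count.

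Leaving out each array in turn gave 2 to 48 probes for E12 against E10, 38 to 138 for E14 against E12, 57 to 136 for E17 against E14, 919 to 1304 for E17 against E10 and 720 to 1001 for any age. The first moved by over 1.5 times without E10 replicates 1 to 4 (4, 3, 7 and 11), E12 replicates 2 and 4 (2 and 4), E14 replicates 1 and 4 (48 and 11) and E17 replicates 1, 2 and 4 (12, 10 and 10). The second moved without E14 replicate 1 (138), and the E17 against E14 count without E17 replicates 2, 3 and 4 (69, 72 and 57). Over 447 runs of the 16 named values none changed sign, while 72 lost the threshold, in 7 of the values and in 0 of those for E17 against E10. The signs say little. The ages compared did not overlap in any of these values, so leaving out arrays could not turn a sign. Several other settings leave the difference itself unchanged. The slope that sets the ratios' direction stayed negative without E10 (-0.203), E12 (-0.153), E14 (-0.217) or E17 (-0.744).

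With the replicate number as a block, the counts were 64 for E12 against E10, 70, 137 and 1414 for the other contrasts and 1071 for any age. It kept 54 of the 56 calls for E14 against E12, the comparison where the numbers were taken as pairs. Elsewhere they were not: over all ages, 13 of 24 same-number pairs of arrays correlated above 0.1 in their deviations (-0.083 to 0.437). Their median was 0.127, against -0.0445 for pairs of unlike number, and 11 of 16 arrays correlated best with one of their own number. Some pairing in the other comparisons is therefore not excluded. Not run, for want of gene names: genes in place of probes, the choice among a gene's probes, every gene-list test, and the planned test of Z-linked genes for sex composition of the pools. Signal over background was not analysed here, so its limit on these values is unknown.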

Other observations

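The test of the probes that rose most was set before its correlations were seen; repeating it without the E14 arrays and by family, comparing positions between batches, and counting splits by pairs were decided afterwards.

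The 30 probes that rose most from E10 to E17 differed in timing. For 17, the largest step was from E12 to E14: their mean was -1.60 ± 0.09 at E10, -1.50 ± 0.18 at E12, 0.07 ± 0.62 at E14 and 0.89 ± 0.07 at E17 (SD over arrays, n = 4). For 11, it came between E14 and E17, with means of -1.26 ± 0.11, -1.30 ± 0.13, -0.94 ± 0.20 and 1.15 ± 0.20. The other 2 rose most between E10 and E12, from -1.30 ± 0.16 to -0.36 ± 0.18.

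A hypothesis is that a timing family may hold several spots of one transcript, or of transcripts that vary together. Deviations from the age means correlated at a median r of 0.67 within families and 0.079 between them, which met the bounds set in advance for both families pooled. The 17 probes carried this: their own median was 0.759, against 0.266 in the 11 probes, which lies under the bound of 0.5. Without the E14 arrays the pooled value was 0.325 within and 0.213 between, and without E14 replicate 1 alone it was 0.485 and 0.178. The evidence therefore rests largely on the E14 arrays, and without gene names the hypothesis stays open.

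Other divisions of the arrays bear on how far chance can account for the counts. For any age, 1 of 100 splits, the real one, gave as many as 901 probes, and the highest of the others gave 2. Only the real split of 35 reached the count for E12 against E10 (28, highest other 0), E17 against E14 (112, highest other 0) and E17 against E10 (1194, highest other 0). That is the smallest share 35 splits can give, not adjusted for the number of comparisons. A mixed split also moves the age difference into the residual variance, which can keep its count low. The splits argue against chance for these at that share and no further. The count for E12 against E10 fell to 2 with 1 array left out. For E14 against E12, 2 of 35 splits gave at least 56, the other being odd against even numbers with 423, so these splits do not exclude chance. That other split parts none of the same-number pairs. Among the 8 splits that part all 4 pairs, as the ages do, the real one gave 56 and the highest other 0 (70 and 0 with the block), and 8 splits are too few for a share under 0.05. The blank-block batches overlapped at E12 over 0.017 of the age scale, less than the SD of 0.069 there, and not at E14, where they lay in the opposite order, so a batch effect on positions within an age stays open. It is argued against for the order of the ages, since the arrays without a blank block alone kept successive ages apart by at least 0.215.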
